A study of Homo sapiens with 11 samples.

How the data were processed

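RNA was measured in 11 libraries of ARPE-19 cells, per the labels, a human retinal pigment epithelium line. Per the labels' protocols, plasmids were delivered with Lipofectamine, RNA was purified with RNeasy Mini columns, and polyadenylated RNA was made into libraries with a NEBNext Ultra RNA kit, for which no strand setting is stated. The 11 libraries form 4 groups: non-transfected cells (2 libraries), cells with the active ATP8 TALEN (3), cells with the ATP8 TALEN whose nuclease is inactive (3), and cells with the active D-loop TALEN (3). A TALEN is a protein built to bind a chosen DNA sequence and joined to a nuclease, and those used here are sent to mitochondria. The design has no inactive D-loop TALEN.

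The authors deposited a table of read counts per gene and a table of normalized values for the same libraries. Per the submitters' processing notes, reads were checked with FastQC, aligned with STAR to hg19 and counted per gene with HTSeq, and DESeq2 was used; versions, the annotation and the strand setting of the counting are not given in the sources used here. The deposited counts are whole numbers for 25382 gene symbols and 5 summary lines that name no gene (no feature, ambiguous, too low quality, not aligned, not unique). These 5 lines held 24.4 to 31.9% of all counts in a library and were kept out of library sizes and tests: not aligned 11.4 to 20.2%, no feature 4.96 to 8.12%, ambiguous 1.99 to 2.22% and not unique 3.53 to 3.97%. The deposited normalized values are on a log2 scale; they equal log2 of the count divided by a size factor plus 1, and the size factors are those that the median-of-ratios method gives when the 5 summary lines are included. Each column of the tables was given its library by name. The columns named wild type were taken as the non-transfected libraries, the only group left without columns, and 1 active D-loop library whose title repeats replicate number 2 was taken as replicate 3 from the code in its title. The number of columns left without a library was 0.

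All tests were run on the deposited counts, whose totals over genes ran from 28623291 to 40657208 per library. Of the 25382 genes, 5047 had 0 counts in every library; filterByExpr by group (minimum count 10, minimum total 15) kept 14600 and left out 10782. Library sizes were scaled by TMM, and edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) was run in 1 fit over the 11 libraries with 1 coefficient per group and no covariate. P-values were adjusted by Benjamini-Hochberg over the 14600 genes, and a gene was called at an adjusted p under 0.05. CPM values use the TMM-scaled library sizes; the mean and SD are over the libraries of a group, and fold changes carry the standard error of the fit. Where a group had 0 counts of a named gene, the fold is taken against a floor of 3 counts over the group. The lower end of the exact 95% interval of the ratio is given with it. With 1 to 3 counts, the ratio is given with its exact 95% interval. These intervals cover counting error only. Among mitochondrial genes, ATP8 with ATP6 and ND4L with ND4 share bases, and reads of MTRNR2L2, MTRNR2L8, MIR6723, HSPA1A, HSPA1B and the HLA genes can be shared with near-identical sequences, so their values are uncertain to that extent. The same holds for antisense genes, since the strand setting is unknown. Counts per gene also do not show whether reads come from a gene's own locus or from a plasmid, and the plasmid sequences were not available.

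The 7 comparisons were each active TALEN against the inactive ATP8 TALEN, both active TALENs together against it, each of the 3 transfected groups against non-transfected cells, and the active TALENs against each other. The gene lists were type I interferon-stimulated genes, MHC class I antigen presentation, genes best known from the interferon-gamma response, nucleic acid sensing and interferon genes, NF-kB targets and inflammatory cytokines, p53 targets, the integrated stress response, mitochondrial chaperones and proteases, the endoplasmic reticulum unfolded protein response, mitochondrial mRNAs, nuclear-encoded oxidative phosphorylation subunits, mitochondrial DNA maintenance, mitochondrial ribosomal proteins, cholesterol synthesis, the cell cycle, glycolysis and hypoxia, NRF2 targets, heat shock, extracellular matrix, retinal pigment epithelium markers, leukocyte markers and endothelial markers. All 659 members of the 22 lists had a line in the table. Each list was tested with camera (limma 3.58.1) at the preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 154 tests of 22 lists in 7 comparisons. Camera compares a list with the other genes.

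Named genes were chosen by rule: per comparison, the 10 largest increases and 10 largest decreases among called genes with a mean log2 CPM of at least 1 and no overlap of CPM between the groups, up to 4 called members of each list with the smallest adjusted p (or the 1 member with the smallest p where none was called), and always the 13 mitochondrial mRNAs and a few genes fixed beforehand, among them IFNB1, ISG15, IFIT1, DDX58, CDKN1A and GDF15. A gene named in 1 comparison may be given in another. Groups, tests, lists, the rule and the alternatives were fixed before the data were examined, except the fit without the non-transfected libraries, which was added after.

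The edgeR step was tested on simulated counts with changed genes at 1.5-fold and 2-fold. Further genes were given a smaller change for the set tests. Their calls entered the total of calls and not the false ones, which lowers the false share. For active against inactive ATP8 TALEN (14189 genes) it recovered 75.3% of 97 genes changed 1.5-fold and 81.6% of 98 changed 2-fold, with 6.6% of calls false. For inactive ATP8 TALEN against non-transfected cells (14119 genes) it recovered 66% of 97 and 83.3% of 96, with 5.59% of calls false, and for the active TALENs against each other (14172 genes) 72.6% of 95 and 82.3% of 96, with 6.35% false. All simulated libraries had the same spread per gene. The 5.59% therefore does not cover the wider spread of the real non-transfected libraries (biological coefficient of variation 0.128). A chi-square test of the counts of the 10 pairs of libraries within a group gave 2.65 to 33.6 per degree of freedom, so every library was counted separately. Shares of counts were compared by exact two-sided permutation tests. The alternatives were DESeq2 (1.42.0) with its Wald test, its size factors inside edgeR, library sizes without mitochondrial genes, no filter and a stricter filter, only the groups compared in the fit, limma on the deposited normalized values, a replicate block, a log2 fold change of at least 1, and leaving out each library in turn. Scaling alternatives moved the median log2 fold change of all genes by at most 0.00733.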

Results

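RNA sequencing was carried out on 11 libraries of ARPE-19 cells to compare cells whose mitochondrial DNA was cut by TALENs with cells that received an inactive TALEN or no plasmid. The active TALENs are named ATP8, after a gene of the mitochondrial genome, and D-loop, after its non-coding control region. The labels place both in 1 class, double-strand breaks in mitochondrial DNA. There were 3 libraries each of active ATP8, active D-loop and inactive ATP8 TALEN, and 2 of non-transfected cells. Gene counts per library ran from 28623291 to 40657208, and 16985 to 17531 genes had at least 1 count. The time between transfection and harvest is not given in the sources used here. Nothing says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The 2 non-transfected libraries differed more from each other (biological coefficient of variation 0.128) than the libraries within each transfected group (0.0382 to 0.0454). The fit used 1 estimate over all groups (0.0615), so standard errors and p-values against non-transfected cells may be too small.

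The transcripts of the mitochondrial genome, the molecule at which the TALENs are aimed, took a smaller share of the counts in every transfected group than in non-transfected cells. The 13 mitochondrial mRNAs took 2.26 ± 0.09% of gene counts in non-transfected cells (SD, n = 2) and 1.39 ± 0.01% with inactive ATP8 TALEN (n = 3). Their share was 0.838 ± 0.142% with active ATP8 TALEN (n = 3) and 1.06 ± 0.04% with active D-loop TALEN (n = 3). All 6 libraries with an active TALEN were below all 3 with the inactive one, with an exact two-sided permutation p of 0.0238. For all 9 transfected libraries against the 2 non-transfected ones the exact p was 0.0364. Both are the smallest these designs allow and became 0.146 after adjustment over 8 comparisons. Single groups of 3 cannot go below 0.1 against each other or below 0.2 against 2 libraries.

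With inactive ATP8 TALEN the loss split at 1 place in the mitochondrial genome. The 9 mRNAs from ATP8 to CYTB in genome order fell against non-transfected cells, with log2 fold changes from -1.67 to -1.44. COX3, a subunit of cytochrome c oxidase, was at 1576 ± 46 CPM in non-transfected cells and at 495 ± 13 CPM with inactive ATP8 TALEN. The 4 mRNAs that lie before ATP8, ND1, ND2, COX1 and COX2, stood between -0.29 and 0.28. Of these, COX2 fell (-0.29 ± 0.09, edgeR adjusted p = 0.00836), and ND2 and COX1 did not pass the test. ND1, a subunit of respiratory complex I, rose (0.28 ± 0.10, adjusted p = 0.0186), a call that was lost with DESeq2. Adjusted over the list alone, 1 of 13 was higher and 11 were lower. As a list the mitochondrial mRNAs passed camera (adjusted p = 8.83e-07), with adjusted p = 0.376 with an estimated correlation.

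With an active TALEN, ND1, ND2, COX1 and COX2 were lower as well. All 13 mRNAs fell against non-transfected cells, by log2 fold changes of -1.91 to -1.13 with active ATP8 TALEN and -1.45 to -0.84 with active D-loop TALEN. Against inactive ATP8 TALEN, the active form lowered 4 of 13, or 9 when adjusted over the list alone. ND1 went from 1113 ± 11 to 355 ± 67 CPM (log2 -1.65 ± 0.09, adjusted p = 5.97e-10), ND2 fell by 1.24, COX2 by 1.01 and COX1 by 0.96 on the log2 scale. The 9 from ATP8 on stood between -0.45 and -0.12. EdgeR called 0 of these 9, with 6 below an unadjusted p of 0.05, 1 called by DESeq2 and 0 by limma. The list passed camera (adjusted p = 3.67e-23), with adjusted p = 0.0662 with an estimated correlation. The count of 4 became 10 without non-transfected replicate 1 or 2 and 8 without active ATP8 replicate 3.

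Active D-loop TALEN also lowered these 4 against inactive ATP8 TALEN, with ND1 at -1.43 ± 0.09, ND2 at -1.01 ± 0.09, COX2 at -0.85 ± 0.08 and COX1 at -0.66 ± 0.07. Another 5 were higher than with inactive ATP8 TALEN, from ND4L (0.43 ± 0.08) to COX3 (0.29 ± 0.08). Adjusted over the list alone, 6 were higher and 4 lower. The count of 9 became 5 without inactive ATP8 replicate 2, active D-loop replicate 2 or active D-loop replicate 3.

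**Figure D1:**
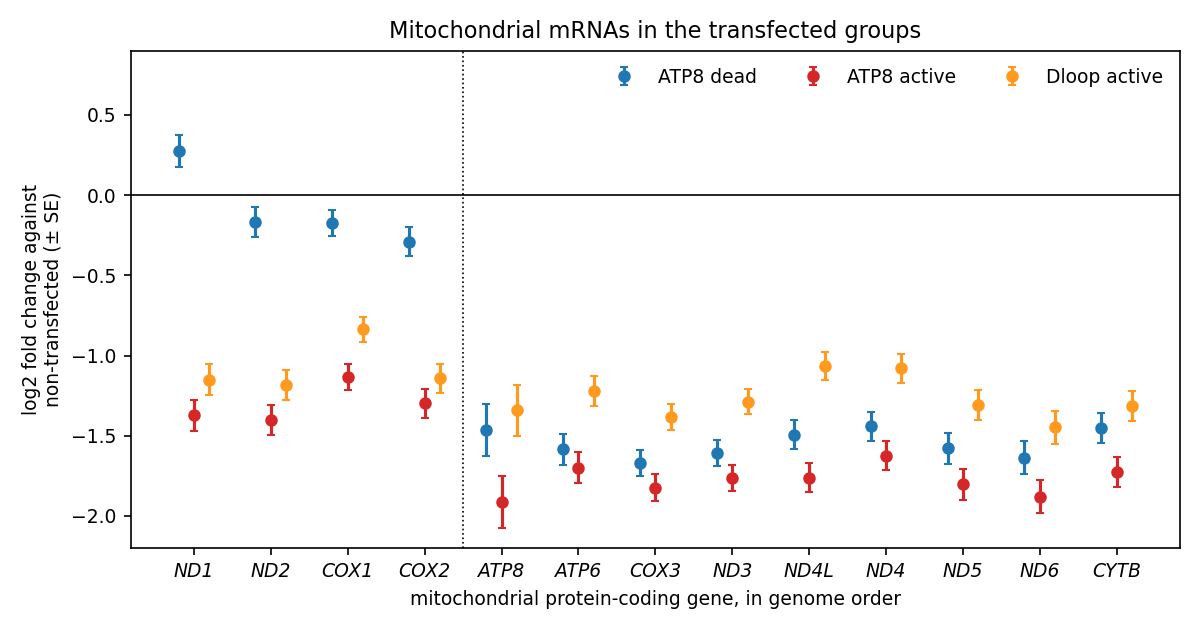
Log2 fold change against non-transfected cells (vertical axis, ± SE from edgeR) of the 13 mitochondrial mRNAs in genome order (horizontal axis) for inactive ATP8, active ATP8 and active D-loop TALEN, with a dotted line between COX2 and ATP8. With inactive ATP8 TALEN the 4 genes left of the line sit between -0.29 and 0.28 and the 9 right of it between -1.67 and -1.44.

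The active ATP8 TALEN, compared with the same TALEN without nuclease activity, raised interferon-stimulated genes. Of 61 type I interferon-stimulated genes measured, 59 rose, with a median log2 fold change of 1.26. RSAD2, an antiviral enzyme, went from 11.2 ± 1.5 to 70.0 ± 2.3 CPM (log2 2.64 ± 0.10, adjusted p = 3.00e-12). MX1, an antiviral GTPase, went from 43.3 ± 3.0 to 202 ± 14 CPM (2.22 ± 0.07, adjusted p = 8.17e-13), and OAS2, which senses double-stranded RNA, from 2.82 ± 0.43 to 18.0 ± 0.6 CPM (2.66 ± 0.13). IFIT1 rose by 1.96 ± 0.09 on the log2 scale, DDX58, the RNA sensor RIG-I, by 1.81 ± 0.06 and ISG15, a ubiquitin-like protein, by 1.40 ± 0.05. Adjusted over the list alone 60 rose, and the list had adjusted p = 5.26e-05 with an estimated correlation. THEMIS2 (2.85 ± 0.18) and BATF2 (2.62 ± 0.19), which are not in this list, were also among the 10 largest increases. IFNB1, the gene of interferon-beta, had 19 counts over the 3 active and 1 over the 3 inactive libraries, a ratio of 16.3 with an exact 95% interval of 2.60 to 679. It did not pass the test (adjusted p = 0.0994).

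Other immune groups also rose with active ATP8 TALEN. In MHC class I antigen presentation 11 of 18 genes rose, or 13 when adjusted over the list alone. Among them were TAP1, a peptide transporter (0.87 ± 0.08), NLRC5, a transactivator of these genes (0.95 ± 0.09), and PSMB9, an immunoproteasome subunit (1.22 ± 0.15). The list passed camera (adjusted p = 1.66e-14), with adjusted p = 0.0606 with an estimated correlation. Of 15 interferon-gamma response genes 7 rose and 1 fell by either adjustment, and adjusted p was 0.00292 with an estimated correlation. APOL6 rose by 1.27 ± 0.08, GBP1, a guanylate-binding protein, by 1.07 ± 0.06 and IRF1, a transcription factor, by 0.78 ± 0.08. Of 18 nucleic acid sensing and interferon genes 4 rose, or 6 when adjusted over the list alone, with adjusted p = 0.00691 with an estimated correlation. These were SAMHD1, a nucleotide hydrolase (1.19 ± 0.07), TLR3, a receptor for double-stranded RNA (1.38 ± 0.14), IFI16, a DNA sensor (1.04 ± 0.11), and TREX1, a DNA exonuclease (0.61 ± 0.10). The MHC class I count was 7 without active ATP8 replicate 1, 2 or 3 or inactive ATP8 replicate 2, and the sensing count was 8 without non-transfected replicate 1 or 2.

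Some NF-kB targets and cholesterol synthesis genes were lower with active than with inactive ATP8 TALEN. The share of reads that did not align was lower too (18.15 ± 0.58% against 20.15 ± 0.09%). Whether the groups took up equal amounts of plasmid was not tested, so unequal transfection cannot be told apart from cutting. Of 23 NF-kB targets 6 fell, or 13 when adjusted over the list alone and 10 without both non-transfected libraries, with a median of -0.27 and adjusted p = 0.0122 with an estimated correlation. CXCL8, a chemokine, fell by 0.70 on the log2 scale. Counts assigned to SOD2, the mitochondrial superoxide dismutase, went from 7841 ± 197 to 6512 ± 176 CPM. Whether they come from the gene's own locus or from a plasmid is not known. Of 23 cholesterol synthesis genes 8 fell, such as INSIG1 (-0.49 ± 0.08) and HMGCS1 (-0.40 ± 0.06), and 11 fell when adjusted over the list alone. Their camera adjusted p was 1.34e-07, and adjusted p = 0.202 with an estimated correlation. The count of 8 became 14 without non-transfected replicate 1 or 2 and without both, 4 without active ATP8 replicate 1, and 5 without active ATP8 replicate 2 or 3, inactive ATP8 replicate 1, 2 or 3, or active D-loop replicate 2.

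Of 15 NRF2 targets 7 rose with active ATP8 TALEN, or 8 when adjusted over the list alone, among them HMOX1, heme oxygenase 1 (0.35 ± 0.06), and GCLC, a glutathione synthesis enzyme (0.42 ± 0.07). Their camera adjusted p was 5.38e-05, and adjusted p = 0.241 with an estimated correlation. This count became 3 without active ATP8 replicate 1 and 4 without active ATP8 replicate 3 or inactive ATP8 replicate 2 or 3. Of 33 cell cycle genes 9 rose and 9 fell, or 15 and 13 when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.604). The mitotic kinases PLK1 (0.42 ± 0.05) and BUB1 (0.35 ± 0.05) rose, while CCNE1, cyclin E1 (-0.70 ± 0.10), and E2F1, a transcription factor of S-phase genes (-0.35 ± 0.05), fell. Of 43 integrated stress response genes 4 rose and 2 fell, or 6 and 4 when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.145). SLC7A11, a cystine transporter, rose by 0.51 ± 0.09, and ATF4, a transcription factor of that response, fell by 0.25 on the log2 scale. The stress response count of 6 became 20, 16 higher and 4 lower, without both non-transfected libraries, 19 without non-transfected replicate 1 or 2, where camera adjusted p was 0.0276 and 0.0266, and 3 without inactive ATP8 replicate 2. PNPT1, the mitochondrial polynucleotide phosphorylase, rose by 0.82 ± 0.05. NEAT1, a long non-coding RNA, fell by 0.91 on the log2 scale.

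Of 29 p53 targets 2 fell with active ATP8 TALEN, or 3 when adjusted over the list alone, with a median of -0.12. The list was lower by camera (adjusted p = 0.00128), and adjusted p = 0.0348 with an estimated correlation. BBC3, a BH3-only apoptosis gene, fell by 0.30 and GADD45A, a growth arrest gene, by 0.34 on the log2 scale, the latter call lost with DESeq2. CDKN1A, the cyclin-dependent kinase inhibitor p21, stood at -0.16 ± 0.05 (adjusted p = 0.0532). The count of 2 became 11 without non-transfected replicate 1 or 2 and without both, 0 without active ATP8 replicate 1 or 3 or inactive ATP8 replicate 1, and 1 without any other library.

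In this comparison edgeR called 830 of 14600 genes, 496 higher and 334 lower, and 84 of them changed at least 2-fold, 75 higher and 9 lower. The count was 2059 (1126 higher, 933 lower) without both non-transfected libraries, an alternative added after the data were seen, and 2187 with only the 2 groups in the fit. It was 2055 and 2043 without non-transfected replicate 1 or 2, 387, 373 and 426 without active ATP8 replicate 1, 2 or 3, and 365 and 368 without inactive ATP8 replicate 2 or 3, while the interferon-stimulated count stayed at 58 to 59 whichever library was left out.

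**Figure D2:**
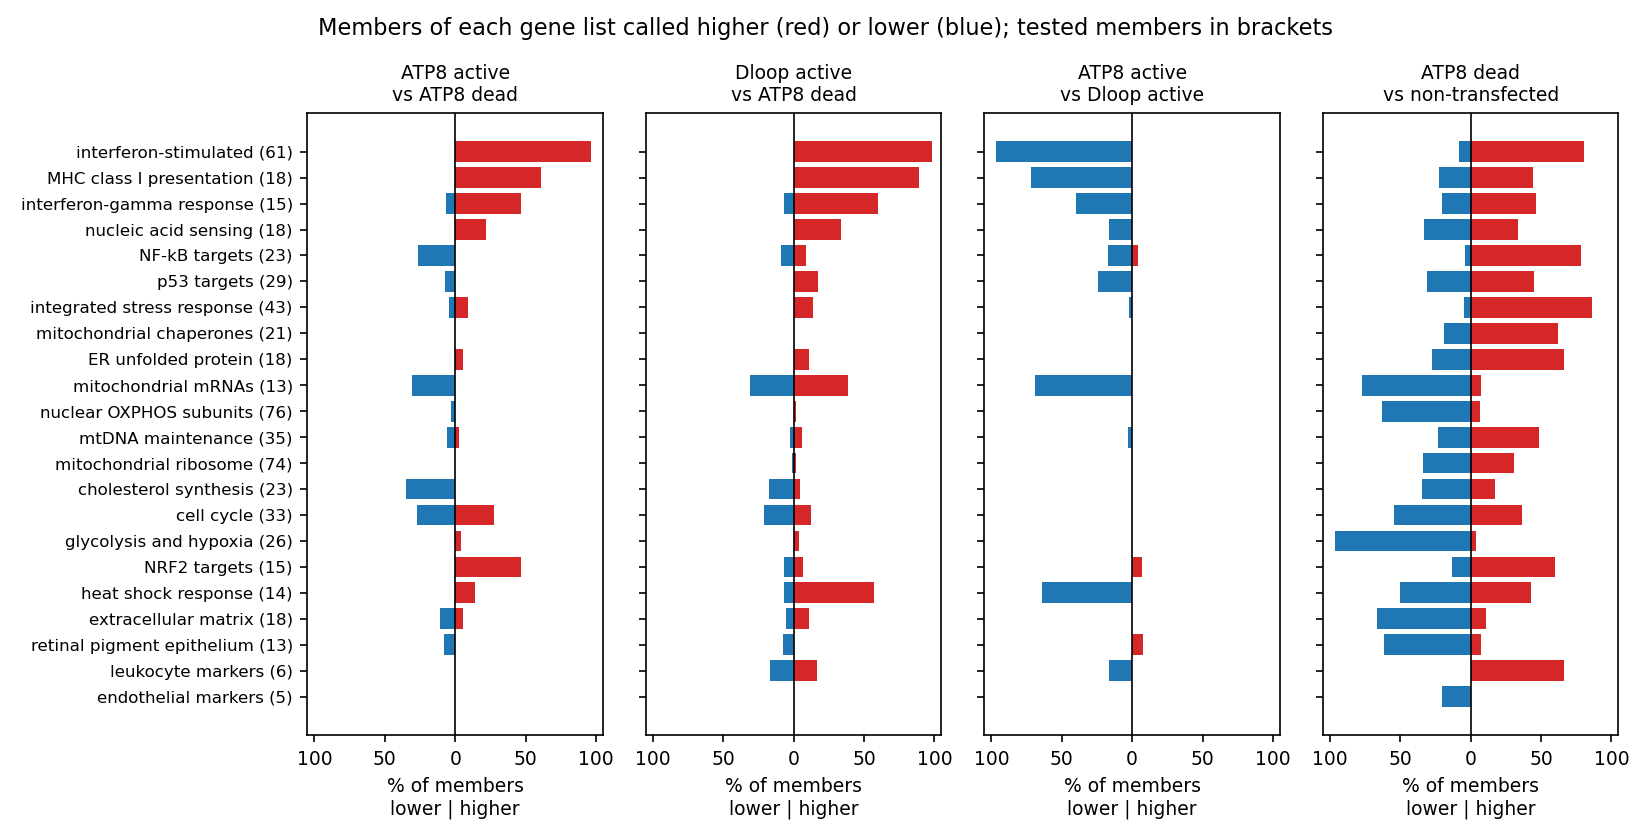
Share of the tested members of each of the 22 gene lists (vertical axis, tested members in brackets) called higher (red, to the right) or lower (blue, to the left) by edgeR, in percent of members (horizontal axis), in 4 comparisons. Interferon-stimulated genes were higher in 59 of 61 with active against inactive ATP8 TALEN and in 60 of 61 with active D-loop TALEN, and lower in 59 of 61 with active ATP8 than with active D-loop TALEN.

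The active D-loop TALEN was compared with the inactive ATP8 TALEN, the only inactive TALEN in the design. It raised 60 of 61 interferon-stimulated genes, or 61 when adjusted over the list alone, with a median log2 fold change of 1.99 and adjusted p = 3.18e-05 with an estimated correlation. RSAD2 reached 196 ± 19 CPM (log2 4.13 ± 0.10, adjusted p = 1.62e-15), MX1 427 ± 17 CPM (3.30 ± 0.07) and IFIT1 700 ± 50 CPM (2.86 ± 0.09). ISG15 reached 312 ± 13 CPM (2.30 ± 0.05) and DDX58 234 ± 15 CPM (2.53 ± 0.06). IFNB1 had 46 counts against 1, a ratio of 39.0 with an exact 95% interval of 6.67 to 1575. It passed the test (adjusted p = 0.00780), a call that was lost with DESeq2.

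Heat shock genes rose too with active D-loop TALEN. Of 14 members 8 rose and 1 fell, or 10 and 1 when adjusted over the list alone, with camera adjusted p = 2.61e-13 and adjusted p = 0.04998 with an estimated correlation. Among them were the Hsp70 genes HSPA1A (1.37 ± 0.08) and HSPA1B (1.24 ± 0.09), the co-chaperone DNAJA1 (0.73 ± 0.05) and HSPH1, an Hsp110 chaperone (0.53 ± 0.05). HSPA6, another Hsp70 gene, which is outside the list, went from 3.17 ± 0.19 to 30.1 ± 1.2 CPM (3.25 ± 0.10, adjusted p = 5.91e-14).

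Of 18 MHC class I genes 16 rose, and 18 when adjusted over the list alone, with adjusted p = 0.00757 with an estimated correlation. TAP1 rose by 1.63 ± 0.08 and HLA-B, a class I heavy chain, by 0.71 ± 0.04. Of 15 interferon-gamma response genes 9 rose and 1 fell by either adjustment (adjusted p = 0.000343 with an estimated correlation), GBP1 by 2.10 ± 0.06 and IRF1 by 1.55 ± 0.08. Of 18 sensing genes 6 rose, or 7 when adjusted over the list alone (adjusted p = 0.00486 with an estimated correlation), including TLR3 (2.45 ± 0.14). Of 23 NF-kB targets 2 rose and 2 fell, or 2 and 3 when adjusted over the list alone. The list was lower by camera (adjusted p = 0.0174), with adjusted p = 0.159 with an estimated correlation and 0.0669 with limma. The cytokine IL6 was higher (1.00 ± 0.18), and CXCL8 (-0.62 ± 0.05) and the counts assigned to SOD2 (-0.76 ± 0.04) were lower. The count of 4 became 8, 2 higher and 6 lower, without non-transfected replicate 1 or 2 and without both, and 7 with only the 2 groups in the fit. Of 29 p53 targets 5 rose and 0 fell, or 6 and 1 when adjusted over the list alone, with a median of 0.07. This list did not pass camera (adjusted p = 0.284), and its count ran from 1 to 7 when 1 library was left out. CDKN1A rose by 0.22 ± 0.05 (adjusted p = 0.00578), ATF3, a stress-induced transcription factor, by 0.38 ± 0.05, and PNPT1 went from 74.0 ± 3.9 to 182 ± 9 CPM. Among the 10 largest decreases were FERMT3, an integrin regulator of blood cells (-1.67 ± 0.23), GATA2, a transcription factor (-1.03 ± 0.18), and MTRNR2L2, which resembles mitochondrial ribosomal RNA (-1.74 ± 0.08).

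EdgeR called 1024 genes here, 640 higher and 384 lower, and 144 changed at least 2-fold, 133 higher and 11 lower. The count was 2165 (1175 higher, 990 lower) without both non-transfected libraries and 2004 with only the 2 groups in the fit. It was 2156 and 2143 without non-transfected replicate 1 or 2, 623 and 606 without inactive ATP8 replicate 2 or 3, and 616 and 567 without active D-loop replicate 2 or 3, while the interferon-stimulated count stayed at 60 whichever library was left out.

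Taking both active TALENs as 1 class, 60 of 61 interferon-stimulated genes rose against inactive ATP8 TALEN by either adjustment, with a median log2 fold change of 1.60 and adjusted p = 3.18e-05 with an estimated correlation. ISG15 stood at 240 ± 80 CPM over the 6 libraries (log2 1.85 ± 0.05) and MX1 at 314 ± 124 CPM (2.76 ± 0.06). MHC class I genes rose in 15 of 18, or 17 when adjusted over the list alone, with adjusted p = 0.0122 with an estimated correlation. ND1, ND2, COX1 and COX2 fell, and were the 4 mitochondrial mRNAs called by either adjustment. In all 1320 genes were called, 762 higher and 558 lower. The count was 2639 (1409 higher, 1230 lower) without both non-transfected libraries, 2607 and 2606 without non-transfected replicate 1 or 2, and 663 and 604 without inactive ATP8 replicate 2 or 3.

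Against inactive ATP8 TALEN, 316 genes were called higher and 165 lower with both active TALENs, and edgeR called 0 in opposite directions. Independent lists of these sizes would share 21.7 and 8.79 genes, a number that leaves out what the shared inactive libraries add. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.698. The median was 0.523 in 20 simulations of unchanged groups that shared simulated inactive libraries. The observed covariance was 0.0819, against 0.0284 in these simulations, a difference of 0.0535. All simulated libraries had the spread of the fit over all groups (0.0615), wider than that of the real inactive libraries (0.0427). The simulated values are therefore not those of the real shared controls. With controls that are not shared, taking the D-loop effect against non-transfected cells, 271 genes were shared as higher (173 expected) and 73 as lower (113 expected), and 381 went in opposite directions. The correlation was then 0.0783 and the covariance 0.0273, but this D-loop effect also holds all that differs between transfected and non-transfected cells. The 3 inactive libraries cannot be split into parts of at least 2, so part of the excess of shared calls may come from the shared controls. Without both non-transfected libraries the shared counts were 666 higher and 512 lower. The higher count was 633 and 636 without non-transfected replicate 1 or 2, 210 and 206 without active ATP8 replicate 1 or 2, and 195 and 198 without inactive ATP8 replicate 2 or 3. The lower count was 518 and 509 without non-transfected replicate 1 or 2, 74, 68 and 73 without active ATP8 replicate 1, 2 or 3, 97, 64 and 57 without inactive ATP8 replicate 1, 2 or 3, and 81 and 93 without active D-loop replicate 2 or 3.

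Set directly against each other, the active TALENs differed mostly in genes that were lower with ATP8 than with D-loop. Interferon-stimulated genes were lower in 59 of 61, with a median log2 fold change of -0.74, and all 61 were lower when adjusted over the list alone. The list had adjusted p = 0.000269 with an estimated correlation. RSAD2 stood at -1.49 ± 0.08, OAS2 at -1.43 ± 0.10, MX1 at -1.08 ± 0.06 and ISG15 at -0.90 ± 0.05. Heat shock genes were lower in 9 of 14, and 12 were lower and 1 higher when adjusted over the list alone. Their median was -0.24, with adjusted p = 0.00757 with an estimated correlation. HSPA1A stood at -1.22 ± 0.07 and HSPH1 at -0.48 ± 0.05. HSPA6 was at 4.05 ± 0.30 CPM with active ATP8 and 30.1 ± 1.2 CPM with active D-loop TALEN (-2.89 ± 0.10, adjusted p = 2.72e-12).

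MHC class I genes were lower with ATP8 than with D-loop in 13 of 18, or 16 when adjusted over the list alone, with adjusted p = 0.00757 with an estimated correlation. Interferon-gamma response genes were lower in 6 of 15, or 9 when adjusted over the list alone, with adjusted p = 0.000343 with an estimated correlation. GBP1 stood at -1.03 ± 0.06. Of the 13 mitochondrial mRNAs 9 were lower, or 12 when adjusted over the list alone, with camera adjusted p = 1.29e-24 and adjusted p = 0.0606 with an estimated correlation. ND4L, a complex I subunit, stood at -0.70 ± 0.08, while ND1, ND2, COX2 and ATP8 lay between -0.57 and -0.16 and did not pass the test. ATF3 was lower (-0.54 ± 0.05). Higher with ATP8 were FERMT3 (1.91 ± 0.22) and the counts assigned to SOD2 (0.50 ± 0.04) and TERT (0.43 ± 0.05). Counts per gene do not show whether SOD2 and TERT reads come from the genes' own loci or from introduced copies. EdgeR called 0 of 26 glycolysis and hypoxia genes (0 below an unadjusted p of 0.05, 0 by DESeq2, 0 by limma).

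Of 29 p53 targets 7 were lower with ATP8 than with D-loop, with a median of -0.22 and adjusted p = 0.00211 with an estimated correlation. Adjusted over the list alone, 17 were lower and 1 higher. CDKN1A stood at -0.38 ± 0.05, AEN, an apoptosis-linked exonuclease, at -0.27 ± 0.04 and RRM2B, a ribonucleotide reductase subunit, at -0.30 ± 0.05. The count of 7 became 14 without non-transfected replicate 1 or 2 and without both, 3 without active ATP8 replicate 1 or 3 or active D-loop replicate 2, and 4 without active D-loop replicate 1.

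In all 243 genes were called between the active TALENs, 34 higher and 209 lower with ATP8. The share called higher, 14.0%, became 32.9% of 566 genes (186 higher, 380 lower) without both non-transfected libraries, and the 2 groups alone gave 586 (191 higher, 395 lower). Without non-transfected replicate 1 or 2 the count was 547 and 546.

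**Figure D3:**
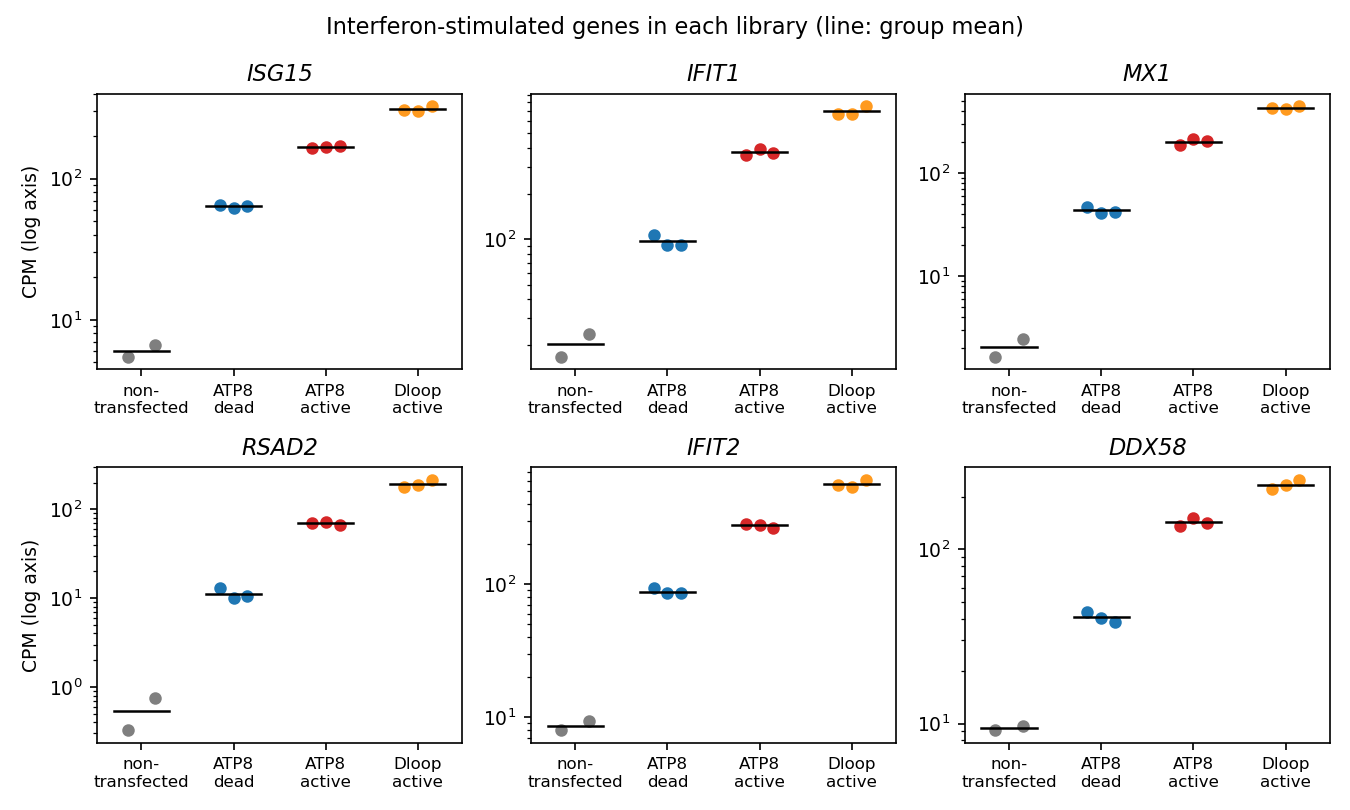
CPM on a log axis (vertical) of 6 interferon-stimulated genes in each of the 11 libraries by group (horizontal), with a line at the group mean. ISG15 means are 6.06 CPM in non-transfected cells, 63.6 CPM with inactive ATP8 TALEN, 167 CPM with active ATP8 TALEN and 312 CPM with active D-loop TALEN.

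Cells with the inactive ATP8 TALEN differed from non-transfected cells in most genes measured. EdgeR called 69.0% of all 14600 genes, 5053 higher and 5026 lower, so a similar share of called members is not particular to a list. NF-kB targets were among the largest increases. Of 23 NF-kB targets 18 rose and 1 fell by either adjustment, with adjusted p = 0.00213 with an estimated correlation. CXCL8 went from 1.55 ± 0.07 to 230 ± 9 CPM (log2 7.21 ± 0.10), and the counts assigned to SOD2 from 46.8 ± 3.8 to 7841 ± 197 CPM (7.39 ± 0.07, adjusted p = 4.16e-22). Counts per gene do not show whether SOD2 reads come from the gene's own locus or from a plasmid. TNFAIP3, an inhibitor of NF-kB signalling, rose by 5.42 ± 0.17, from 2.2 and 5.4 CPM in the non-transfected libraries. PTX3, a secreted pattern recognition protein outside the list, rose by 6.32 ± 0.08. Of 43 integrated stress response genes 37 rose and 2 fell by either adjustment, with a median of 1.59 and adjusted p = 0.0112 with an estimated correlation. CHAC1, a glutathione-degrading enzyme, rose by 5.97 ± 0.12, TRIB3, a pseudokinase induced by ATF4, by 4.49 ± 0.08 and ATF3 by 3.89 ± 0.07.

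Interferon-stimulated genes were already higher with inactive ATP8 TALEN than in non-transfected cells. Of 61 genes 49 rose and 5 fell by either adjustment, with a median of 1.06. The list had camera adjusted p = 4.31e-18 and adjusted p = 0.127 with an estimated correlation. MX1 rose by 4.41 ± 0.12, ISG15 by 3.39 ± 0.08 and IFIT1 by 2.26 ± 0.11. Of 18 sensing genes 6 rose and 6 fell by either adjustment, and the list did not pass camera (adjusted p = 0.751). MAVS, the adaptor of RNA sensing on mitochondria, stood at -1.04 ± 0.05 and TREX1 at -1.67 ± 0.10.

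Glycolysis and hypoxia genes were lower with inactive ATP8 TALEN, with 25 of 26 lower and 1 higher by either adjustment and a median of -1.05. The list had camera adjusted p = 2.06e-14 and adjusted p = 0.145 with an estimated correlation. NDRG1, a hypoxia-induced gene, stood at -2.32 ± 0.06, the glucose transporter SLC2A1 at -1.85 ± 0.06 and the lactate dehydrogenase LDHA at -1.11 ± 0.05. Nuclear-encoded respiratory chain subunits fell in 48 of 76 and rose in 5 by either adjustment, with a median of -0.21. Their camera adjusted p was 0.00873, it became 0.0606 without non-transfected replicate 2, and adjusted p = 0.604 with an estimated correlation. Of 13 retinal pigment epithelium markers 8 fell and 1 rose by either adjustment, with camera adjusted p = 0.0302 and adjusted p = 0.134 with an estimated correlation. The transcription factors MITF (-1.05 ± 0.07) and OTX2 (-1.51 ± 0.08) were among them. ELF3, an epithelial transcription factor (-6.72 ± 0.26), EDN2, an endothelin (-5.21 ± 0.33), and ATOH8 (-4.87 ± 0.25) were the 3 largest decreases by edgeR.

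Other mitochondrial and stress lists went both ways, as did all genes, of which 69.0% were called. Of 35 mitochondrial DNA maintenance genes 17 rose and 8 fell by either adjustment, with camera adjusted p = 0.0113 and adjusted p = 0.0606 with an estimated correlation, and the helicase gene C10orf2 rose by 1.90 ± 0.07. Of 18 unfolded protein response genes 12 rose and 5 fell by either adjustment, with camera adjusted p = 0.00862 and adjusted p = 0.228 with an estimated correlation. HSPA5, the chaperone BiP, rose by 1.31 ± 0.08. Of 15 NRF2 targets 9 rose and 2 fell by either adjustment, and HMOX1 rose by 1.65 ± 0.07. The NRF2 list had camera adjusted p = 0.0153, 0.14 without non-transfected replicate 1, and adjusted p = 0.462 with an estimated correlation. Of 21 mitochondrial chaperones and proteases 13 rose and 4 fell (camera adjusted p = 0.145), HSPA9, a mitochondrial Hsp70, by 1.53 ± 0.04. Of 74 mitochondrial ribosomal protein genes 23 rose and 25 fell (camera adjusted p = 0.721), and of 14 heat shock genes 6 rose and 7 fell (camera adjusted p = 0.486), in all 3 lists by either adjustment.

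Growth, matrix and remaining immune lists did not pass camera with all libraries. Of 29 p53 targets 13 rose and 9 fell, or 10 fell when adjusted over the list alone, and PMAIP1, another BH3-only gene, rose by 3.21 ± 0.15. This list had camera adjusted p = 0.0266 without non-transfected replicate 2. Of 33 cell cycle genes 12 rose and 18 fell, with TOP2A, a DNA topoisomerase, at -1.43 ± 0.06. Of 18 extracellular matrix genes 2 rose and 12 fell, with COL1A1, a type I collagen chain, at -2.71 ± 0.14, and this list had camera adjusted p = 8.45e-05 without non-transfected replicate 2. Of 23 cholesterol synthesis genes 4 rose and 8 fell, of 18 MHC class I genes 8 rose and 4 fell, and of 15 interferon-gamma response genes 7 rose and 3 fell, the last with camera adjusted p = 0.0317 without non-transfected replicate 2. Among markers of other cell types, 4 of 6 tested leukocyte markers rose and 1 of 5 tested endothelial markers fell, the latter count 2 without inactive ATP8 replicate 3. These lists have 16 and 12 members, and the rest had too few counts to be tested. CD14, a monocyte receptor, had 3 counts in non-transfected cells and 129 with inactive ATP8 TALEN, a ratio of 36.4 with an exact 95% interval of 12.2 to 179. ITGAM, a myeloid integrin, and TMEM119 had 0 counts in non-transfected cells. With inactive ATP8 TALEN they were 9.04-fold and 98.6-fold higher, taking 3 counts over the group as the floor. The lower ends of the exact 95% intervals were 6.94 and 79.7. Mean levels with inactive ATP8 TALEN were low, at 1.41 CPM for CD14, 0.35 CPM for ITGAM and 3.79 CPM for TMEM119. Adjusted over the list alone, the counts of these lists other than p53 were the same.

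EdgeR called 10079 of 14600 genes in this comparison, 5053 higher and 5026 lower, and 3017 changed at least 2-fold. With only these groups in the fit, 9310 genes were called. Reads that did not align were 20.2 ± 0.1% with inactive ATP8 TALEN and 11.5 ± 0.1% in non-transfected cells. No library of cells given an empty or unrelated plasmid is in the design, so transfection, TALEN expression and handling cannot be separated.

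Against non-transfected cells the active TALENs gave higher interferon-stimulated, NF-kB and stress response genes. Members of these lists also rose with inactive ATP8 TALEN, so a rise against non-transfected cells is not particular to the active TALENs. Against inactive ATP8 TALEN, median log2 fold changes with active ATP8 and active D-loop TALEN were 1.26 and 1.99 for interferon-stimulated genes. They were -0.27 and -0.09 for NF-kB targets and 0.05 and 0.08 for stress response genes. With active ATP8 TALEN 60 of 61 interferon-stimulated genes rose by either adjustment, with a median of 2.50 and adjusted p = 0.00757 with an estimated correlation. With active D-loop TALEN 60 of 61 rose by either adjustment, with a median of 3.21 and adjusted p = 0.00483 with an estimated correlation. ISG15 rose by 4.79 ± 0.08 with ATP8 and 5.69 ± 0.08 with D-loop on the log2 scale. IFNB1, at 0 counts in non-transfected cells, was 4.61-fold and 11.0-fold higher, taking the same floor of 3 counts over the group. The lower ends of the exact 95% intervals were 3.40 and 8.61. NF-kB targets rose in 17 of 23 with ATP8 and 18 of 23 with D-loop, with 2 lower in each, and 17 and 20 rose when adjusted over the list alone. Their adjusted p was 0.00314 and 0.00292 with an estimated correlation. The counts assigned to SOD2 rose by 7.12 ± 0.06 and 6.62 ± 0.06. Stress response genes rose in 37 of 43 in each, with 3 and 2 lower by either adjustment, and adjusted p was 0.0101 and 0.0109 with an estimated correlation. TRIB3 rose by 4.75 ± 0.08 and 4.63 ± 0.08. Glycolysis and hypoxia genes fell in 24 of 26 in each by either adjustment, with 1 higher, and adjusted p = 0.136 and 0.15 with an estimated correlation.

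MHC class I genes rose against non-transfected cells in 13 of 18 with active ATP8 TALEN and in 14 of 18 with active D-loop TALEN, and fell in 2 and 1. Adjusted over the list alone, 13 and 15 rose and 2 and 1 fell. Adjusted p was 0.46 and 0.22 with an estimated correlation. Of all 14600 genes edgeR called 9952 (68.2%) with active ATP8 TALEN, 5021 higher and 4931 lower. With active D-loop TALEN it called 10038 (68.8%), 5101 higher and 4937 lower. Reads that did not align were 18.2 ± 0.6% and 16.1 ± 1.3%.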

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

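All tests of explanations in this part were chosen after the results they test were seen.

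The direct comparison of the active TALENs, a test of the difference itself, called 243 genes, and it is why 4 gene groups are listed here. With ATP8 lower than with D-loop were 59 of 61 interferon-stimulated genes and 9 of 14 heat shock genes. Also lower were 9 of 13 mitochondrial mRNAs (6 to 12 when 1 library was left out) and 7 of 29 p53 targets. The p53 count became 14 without non-transfected replicate 1 or 2, 3 without active ATP8 replicate 1 or 3 or active D-loop replicate 2, and 4 without active D-loop replicate 1. The count of 243 became 547 and 546 without non-transfected replicate 1 or 2. Reads that did not align, which no comparison of genes uses, made up 18.14% in transfected libraries and 11.47% in non-transfected ones, with an exact two-sided permutation p of 0.0364 (n = 9 and 2), the smallest this design allows and 0.146 after adjustment over 8 comparisons. They made up 14.63 to 18.75% in the 6 libraries with an active TALEN and 20.05 to 20.23% in the 3 with the inactive one. The exact permutation p was 0.0238 there, again the smallest possible and 0.146 after the same adjustment.

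Interferon-stimulated genes were higher with active D-loop than with active ATP8 TALEN. A difference in scaling between libraries would move this list with all genes, but its median minus that of all genes was -0.739 on the log2 scale (active ATP8 against active D-loop). More RNA from outside the reference, such as from the plasmid, could raise the unaligned share with D-loop. Its highest value there, 17.02%, was below the lowest with active ATP8 TALEN, 17.6%. This share holds unaligned reads of any origin, and plasmid reads that match a human gene can align. It therefore cannot decide whether the groups differed in plasmid. An effect of the D-loop TALEN protein apart from its cut could also account for the pattern, since 9 heat shock genes were higher with D-loop too. The design has no inactive D-loop TALEN, so such an effect cannot be told apart from one of where the mitochondrial DNA is cut, which is a hypothesis that was not tested.

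With inactive ATP8 TALEN the mitochondrial mRNAs from ATP8 on were lower than in non-transfected cells, and those before it were near the level there. Scaling between libraries would move all 13 alike, but the median from ATP8 on minus that of the genes before it was -1.408 on the log2 scale. Reads shared with nuclear copies would hold up all genes with a copy, but ATP8, ATP6 and COX3, which have annotated copies in the same nuclear block as the 4 genes before ATP8, had a median of -1.584. A candidate explanation is that the bound inactive TALEN stops transcription of the heavy strand at its site. ND6, which is read from the other strand, stood at -1.636, but the strand of its counts is not known, so this cannot be told apart from other causes of loss.

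The 9 libraries of the comparison of both active TALENs with the inactive one were regrouped in 84 ways. The real grouping called 1825 genes in a fit of these libraries with the 6 active ones as a single group (2639 when each TALEN had its own mean). The highest other called 360, and 1 of 84, the real one, called as many. Of interferon-stimulated genes the real grouping called 60, and other groupings called at most 46. Every other grouping puts active and inactive libraries together, so the difference between them widens the spread and lowers the count. Chance differences between cultures are not excluded by this regrouping, also because the spread between these libraries may be technical. For groups of 3 against 3 there are only 10 splits, too few for a share under 0.05, and 1 of 10, the real one, was as large in each. The other splits mix the 2 groups here too. The real and highest other counts were 2187 and 0 for active against inactive ATP8 TALEN, 2004 and 0 for active D-loop against inactive ATP8 TALEN, and 586 and 0 for active ATP8 against active D-loop TALEN.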

How the results depend on the processing

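All alternatives were chosen before the data were examined except the fit without both non-transfected libraries, which was added after. Counts of called genes among the transfected groups were larger without the non-transfected libraries, whose spread enters the shared estimate: the biological coefficient of variation was 0.0615 with all libraries and 0.0422 without these 2. Within the non-transfected libraries it was 0.128, so p-values against them may be too small. Against non-transfected cells, fits of only the groups compared called 9318 genes for active ATP8, 9362 for active D-loop and 9310 for inactive ATP8. With only the groups compared in the fit, called genes numbered 2187 for active against inactive ATP8 TALEN, 2004 for active D-loop against inactive ATP8, 2639 for both active TALENs against inactive ATP8 and 586 for active ATP8 against active D-loop. Without both non-transfected libraries these were 2059, 2165, 2639 and 566. The 4 mitochondrial transcripts called for active against inactive ATP8 became 11 with no filter, 10 with only the groups compared and 10 without both non-transfected libraries. The 316 genes shared by the active TALENs as higher became 624 with only the groups compared, 666 without both non-transfected libraries and 71 at a log2 fold change of at least 1. The 165 shared as lower became 526, 512 and 5, and 73 with the D-loop effect taken against non-transfected cells. The 73 were fewer than the 113 expected of independent lists, whereas the 165 were more than the 8.79 expected. The interferon-stimulated list for inactive ATP8 TALEN against non-transfected cells went from an adjusted p of 4.31e-18 to 0.127 with an estimated correlation.

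Leaving out 1 library at a time, called genes ran from 365 to 2055 for active against inactive ATP8, 567 to 2156 for active D-loop against inactive ATP8, 604 to 2607 for both active against inactive ATP8 and 177 to 547 for active ATP8 against active D-loop. Against non-transfected cells they ran from 9342 to 9911 for active ATP8, 9461 to 10015 for active D-loop and 9529 to 10015 for inactive ATP8. Called mitochondrial transcripts ran from 4 to 10 for active against inactive ATP8 and 5 to 11 for active D-loop against inactive ATP8. Called interferon-stimulated genes ran from 58 to 59 for active against inactive ATP8, 56 to 60 for active ATP8 against active D-loop and 49 to 54 for inactive ATP8 against non-transfected cells. Shared genes ran from 195 to 636 higher and 57 to 518 lower. Where a group was left with 1 library, it was assumed to vary like the other groups.

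Over the alternatives other than leaving out 1 library, 5842 of 5973 results for named genes kept their direction and call, 78 gained the call and 53 lost it. Leaving out single libraries, 7339 of 7777 kept it, 58 gained it and 380 lost it. Of set tests, 1485 of 1628 kept their call, 82 gained it and 61 lost it, and 1646 of 1694 kept it when 1 library was left out, with 30 gained and 18 lost. With an estimated correlation 45 of 154 set tests lost their call.

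With replicate number as a block, 0 of 7 counts of called genes changed by over 1.5 times. Of set tests 1 of 154 changed, the stress response list between the active TALENs (adjusted p = 0.0544). Of named genes 19 of 707 changed, 18 losing and 1 gaining the call with the block. Whether the numbers pair the samples was not settled. After removing group means, 0 of 15 pairs with the same number correlated above 0.1 (r from -0.0172 to 0.0477). The 30 other pairs ran from -0.0477 to 0.0414. Only 2 of 11 samples correlated best with their own number in every other group. Samples of replicate 3 could not do so, because non-transfected cells have no replicate 3.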

Other observations

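The levels of genes in this part were looked at after the results were seen.

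Further members of the gene lists, and 1 gene outside them, differed between inactive ATP8 TALEN and non-transfected cells. ICAM1, an adhesion molecule of the interferon-gamma list, rose from 5.29 ± 1.29 to 32.4 ± 1.2 CPM (log2 2.61 ± 0.12, SD with n = 2 and 3), and ZEB1, a repressor of epithelial genes in the matrix list, from 17.6 ± 0.2 to 67.4 ± 1.9 CPM (1.94 ± 0.06). MYO7A, an unconventional myosin outside the lists, went from 68.0 ± 14.8 to 2.74 ± 1.24 CPM (-4.64 ± 0.24). CA9, a carbonic anhydrase induced by hypoxia, went from 620 ± 55 to 207 ± 3 CPM (-1.58 ± 0.05). KIF20A, a mitotic kinesin, fell by 1.66 on the log2 scale while CDT1, a replication licensing factor, rose by 1.34 ± 0.07.

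Counts assigned to TERT were among the highest in all 11 libraries, at 741.8 to 1828 CPM and ranks 36 to 146 of 25382 genes. Its mean was 1729 ± 139 CPM in non-transfected cells, 1105 ± 29 CPM with inactive ATP8 TALEN, 1099 ± 28 CPM with active ATP8 TALEN and 814 ± 65 CPM with active D-loop TALEN. Of its neighbours in the genome, SLC6A18, SLC6A19 and MIR4457 had 0 counts in every library, and CLPTM1L had means from 174 ± 15 CPM in non-transfected cells to 247 ± 3 CPM with inactive ATP8 TALEN. Counts per gene do not show whether the reads come from the gene's own locus or from an introduced copy, the labels as used here name no introduced copy, and the labels are the only source for the identity of the line.

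In counting terms, 5 genes had 0 counts in both non-transfected libraries and at least 10 in every transfected library, and 0 genes the other way round. These were TMEM119, CSF2, SLC17A8, BTK and NCF1, with highest levels of 4.21, 2.20, 1.91, 1.64 and 1.05 CPM in any library.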
